A study of Mus musculus with 18 samples.

How the data were processed

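Spinal cord RNA of mice at postnatal day 7 was sequenced in 18 libraries, 3 in each of 6 groups. The groups were wild type (WT), AR-24Q, AR-97Q, AR-97Q given testosterone, AR-97Q given a scrambled antisense oligonucleotide (Scramble-ASO) and AR-97Q given antisense oligonucleotide number 3 against Rest4 (Rest4-ASO3). AR-24Q and AR-97Q are transgenic mice whose androgen receptor carries 24 or 97 glutamines. Testosterone was given under the skin and the oligonucleotides into the brain ventricles, both at postnatal day 1, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

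The values deposited by the authors are TPM, transcript abundances scaled for transcript length to a fixed total, with 1 value per gene symbol and library, in 3 tables of 45777 gene rows. One table holds the 9 libraries of the WT, untreated AR-97Q and testosterone groups, another the 6 oligonucleotide libraries, and the last the 3 AR-24Q libraries. The unit was read from the values, which sum to 1000000 within 0.01 in each library as deposited, and from StringTie being among the tools named. FastQC, Trimmomatic, HISAT2 and StringTie, without versions, and the genome build mm10 are given per the submitters' processing notes. Libraries were made with a stranded mRNA kit, per the labels' protocols. The annotation, filters and settings are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval or detection floor is given. TPM is relative to the total of each library, so a change in a few abundant RNAs moves all other values the opposite way.

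The design fixed before the data were examined had one branch for counts and another for normalized values, and the branch for normalized values was used because the tables hold TPM. Values were analysed as log2(TPM + 1), and log2 differences are on that scale, which understates the change of genes at a few TPM. Genes with a mean of at least 1 TPM over the libraries fitted were tested with limma (version 3.58.1, R version 4.3.3) by moderated statistics with an intensity trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 libraries of the first table entered one fit, and the 6 oligonucleotide libraries another. Tests were made only within a table. AR-24Q is alone in its table, so its values are set beside the other groups without a test. Nothing in the labels says that the samples come from separate animals, so the p-values measure the spread between these samples, which may be technical. No pair of libraries within a table held identical values, and the correlation of log2 values between libraries of a group ranged from 0.977 to 0.994.

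Before the data were examined, 30 gene lists were fixed, covering targets of REST, neuronal functions, pathways and markers of cell types and of position along the body axis. Lists with at least 3 tested members, 27 in each comparison, were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were added views. Called members were counted over all genes tested and adjusted over the list alone. The genes named follow a rule fixed at the same time. It takes the target genes Ar, Rest and Srrm4, and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap and whose higher group has a mean of at least 1 TPM. It also takes up to 4 members with the smallest p of each list that passed its test or had called members, and the 5 genes with the smallest p where fewer than 5 passed. Unnamed gene models are named only where they are among the 3 largest. The genes called in an alternative that called 5 or fewer were named after their values were seen.

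Relations between comparisons were measured as correlations over genes, which are not independent replicates. For comparisons that share libraries, 100 simulations with no effect gave the reference for correlations and covariances, and 20 for overlaps of called genes. After the data were seen, 100 more were made with each library of the testosterone relation left out. For the oligonucleotide comparison, the 10 splits of its 6 libraries did. The test was checked on simulated data with 200 changed genes. Genes varied independently there, with no shift shared within a library and with rises and falls equally likely. The shares found in this way need not hold for the real libraries. For AR-97Q against WT, over 16121 genes, 53.4% of changes of 0.5 on the log2 scale were recovered, 93.4% of changes of 1 and 99.7% of changes of 2, with a false share of 4.4%. For Rest4-ASO3 against Scramble-ASO, over 15963 genes, the shares were 53.1%, 91.3% and 97.9%, with a false share of 3.7%.

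A spreadsheet had turned 26 symbols of one table into dates. Of these, 22 were restored and 4, which 2 symbols shared, were left out, with up to 0.012% of the TPM of a library. Gene positions, GC content and transcript lengths come from the GENCODE mouse annotation, release 21, on GRCm38, the assembly that mm10 names. Of the 16117 genes tested in the first table, 15269 (94.7%) had an entry. Alternatives chosen at the start were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, a fold threshold, only the 2 groups compared and each replicate left out in turn, with median-of-ratios scaling for AR-24Q and a minimum of 10 TPM for the relation of the oligonucleotide and transgene effects. Rescaling without mitochondrial and ribosomal RNA and, for the tested comparisons, median-of-ratios scaling, a minimum mean of 10 TPM, leaving out small RNA genes and removing each library's trend on GC content and transcript length were added after the data were seen.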

Results

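Gene expression in the spinal cord of mice at postnatal day 7 was compared between WT, AR-97Q, AR-24Q, and AR-97Q mice treated with testosterone, Scramble-ASO or Rest4-ASO3, with 3 libraries in each of 6 groups. The expanded glutamine stretch of the androgen receptor is known as the cause of spinal and bulbar muscular atrophy, a disease of motor neurons. Values are TPM, whose depth is unknown. Each library had between 15685 and 16430 genes at 1 TPM or more. Mitochondrial transcripts made up 12.4% to 20.96% of a library, the most in WT replicate 1.

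The first comparison asked what the expanded transgene changed against WT. Genes of myelin were lower in AR-97Q. Mbp (chromosome 18, 82475146 to 82585637), which encodes a main protein of the myelin sheath, had 6405 ± 1249 TPM in AR-97Q and 11948 ± 355 in WT (SD, n = 3), a log2 difference of −0.92 ± 0.13 (SE; limma, adjusted p = 0.041). Mag (chromosome 7, 30899176 to 30914873), an adhesion protein of myelin, had 531.9 ± 62.4 and 866.2 ± 29.5 TPM (SD, n = 3; log2 difference −0.71). Cldn11 differed by −0.71, Mal by −0.87 and Opalin by −1.11 on the log2 scale. Of the 18 oligodendrocyte and myelin markers, 15 were called lower, 17 when adjusted over the list alone, and the list mean was −0.66 (camera, adjusted p = 1.2e-35). That list had adjusted p = 0.22 with an estimated correlation, and fry gave an adjusted p of 0.048. The other 8 lists that passed camera in this comparison did not pass fry (adjusted p = 0.052 to 0.36).

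The genes listed as precursor markers of the same lineage, not all of them particular to precursors, had smaller differences. All 5 were negative with a mean of −0.21, none was called and 3 passed when adjusted over the list alone (camera, adjusted p = 0.00013; adjusted p = 0.27 with an estimated correlation). Among them, Olig1 had 266.8 ± 4.2 TPM in AR-97Q and 331.5 ± 33.6 in WT (SD, n = 3), and Sox10 had 104.5 ± 6.0 and 121.6 ± 13.02 (SD, n = 3). Of 14 genes of cholesterol synthesis, 13 were negative, 2 were called lower and 11 passed when adjusted over the list alone (camera, adjusted p = 2.8e-16; adjusted p = 0.22 with an estimated correlation). The called genes were Ldlr, the receptor that takes up low-density lipoprotein, with 23.9 ± 1.1 against 34.4 ± 2.8 TPM, and Lss, a synthesis enzyme, with 51.4 ± 1.6 against 67.2 ± 5.2 (SD, n = 3). Of 11 astrocyte markers, 8 were negative, S100b was called lower and 3 passed when adjusted over the list alone (camera, adjusted p = 4.6e-06; adjusted p = 0.27 with an estimated correlation). All 9 vascular markers were negative, none was called and 2 passed when adjusted over the list alone (camera, adjusted p = 3.6e-05; adjusted p = 0.32 with an estimated correlation). Of 9 meningeal and fibroblast markers 7 were negative, and none was called (camera, adjusted p = 0.0047; adjusted p = 0.52 with an estimated correlation). Without AR-97Q replicate 2 the meningeal list no longer passed, with a mean of −0.10.

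REST represses neuronal genes outside neurons. Of its 33 listed target genes, 32 had positive differences in AR-97Q, with a mean of 0.18, none was called and 3 passed when adjusted over the list alone (camera, adjusted p = 0.00061; adjusted p = 0.78 with an estimated correlation). The median of all genes was 0.07. Glutamatergic, inhibitory and presynaptic lists, which share members with the REST list, had 19 of 22, 18 of 20 and 18 of 20 positive. Their means were 0.14, 0.14 and 0.12, and they did not pass (camera, adjusted p = 0.077 for each). Of 21 voltage-gated channel genes 16 were positive, and of 14 motor neuron markers 5. Dner had 269.8 ± 19.0 TPM in AR-97Q and 224.7 ± 10.6 in WT (SD, n = 3), and Scn3b had 93.6 ± 6.2 and 74.6 ± 9.5 (SD, n = 3). The REST target list rested on WT replicate 1, since without it the mean was 0.07 and the test was not passed. The mean was 0.11 with median-of-ratios scaling and with the GC content and length trend removed. That library also carried the highest mitochondrial share. Without WT replicate 1, the list of immediate early genes, with a mean of −0.20 (camera, adjusted p = 0.0047; adjusted p = 0.27 with an estimated correlation), had a mean of −0.10 and did not pass, nor did it over genes of at least 10 TPM, with −0.0048. The cell cycle list, with a mean of 0.18 (camera, adjusted p = 0.033; adjusted p = 0.75 with an estimated correlation), did not pass without WT replicate 2, WT replicate 3 or AR-97Q replicate 3, with means of 0.19, 0.12 and 0.15, or over genes of at least 10 TPM, with 0.13. Its mean was 0.11 with quantile normalization and 0.12 with median-of-ratios scaling or the GC content and length trend removed. Rest itself (chromosome 5, 77265491 to 77286432) had 5.26 ± 0.42 TPM in AR-97Q and 5.20 ± 0.37 in WT (SD, n = 3; limma, adjusted p = 0.96). Srrm4, a splicing factor that promotes the neuronal Rest4 form of Rest, had 11.2 ± 2.2 and 9.52 ± 1.24 (SD, n = 3; limma, adjusted p = 0.50). Mouse Ar had 1.31 ± 0.11 and 0.98 ± 0.31 TPM (SD, n = 3; limma, adjusted p = 0.50), a row that does not separate reads of the transgene from those of the mouse gene.

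Among genes higher in AR-97Q, Islr2 had 13.9 ± 2.0 TPM against 8.09 ± 0.48, Cxadr, a cell adhesion receptor, had 89.96 ± 7.37 against 57.8 ± 7.7, and Cyp26b1, which degrades retinoic acid, had 7.62 ± 1.49 against 4.21 ± 0.56 (SD, n = 3). Fsip1 had the largest rise, 1.02 on the log2 scale. Cdkn1a, an inhibitor of the cell cycle from the list of steroid receptor responsive genes, was its called member, at 59.1 ± 4.2 against 42.8 ± 0.9 TPM (SD, n = 3). That list did not pass (camera, adjusted p = 0.65), and its mean of 0.02 had the opposite sign to its median and test. The gene model LOC115488130 was listed at 0 in the 3 AR-97Q libraries and at 6.88 ± 1.00 TPM in WT (SD, n = 3). The AR-97Q group given testosterone lay 1.80 above untreated AR-97Q for this gene on the log2 scale. Its absence was thus not shared by all libraries with the transgene. In all, 112 of 16117 genes were called, 41 higher and 71 lower, against 38 higher and 109 lower with median-of-ratios scaling. At an unadjusted p under 0.05 there were 2443 genes, 71.4% of them higher, a share that was 60.6% rescaled without mitochondrial and ribosomal RNA, 47.9% with quantile normalization, 45.1% with median-of-ratios scaling and 46.7% with the GC content and length trend removed. The smallest adjusted p from limma was 0.041, close to the threshold. The count was 0 without WT replicate 1, 0 without WT replicate 2, 2 without WT replicate 3, 216 without AR-97Q replicate 1, 0 without AR-97Q replicate 2 and 0 without AR-97Q replicate 3. Of the 216, 90 were among the 112, and of the 2, Cited2 and H1f2, neither was. It was 1 with the 2 groups alone, the gene LOC115488130, and 0 with no filter on low values.

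**Figure D1:**
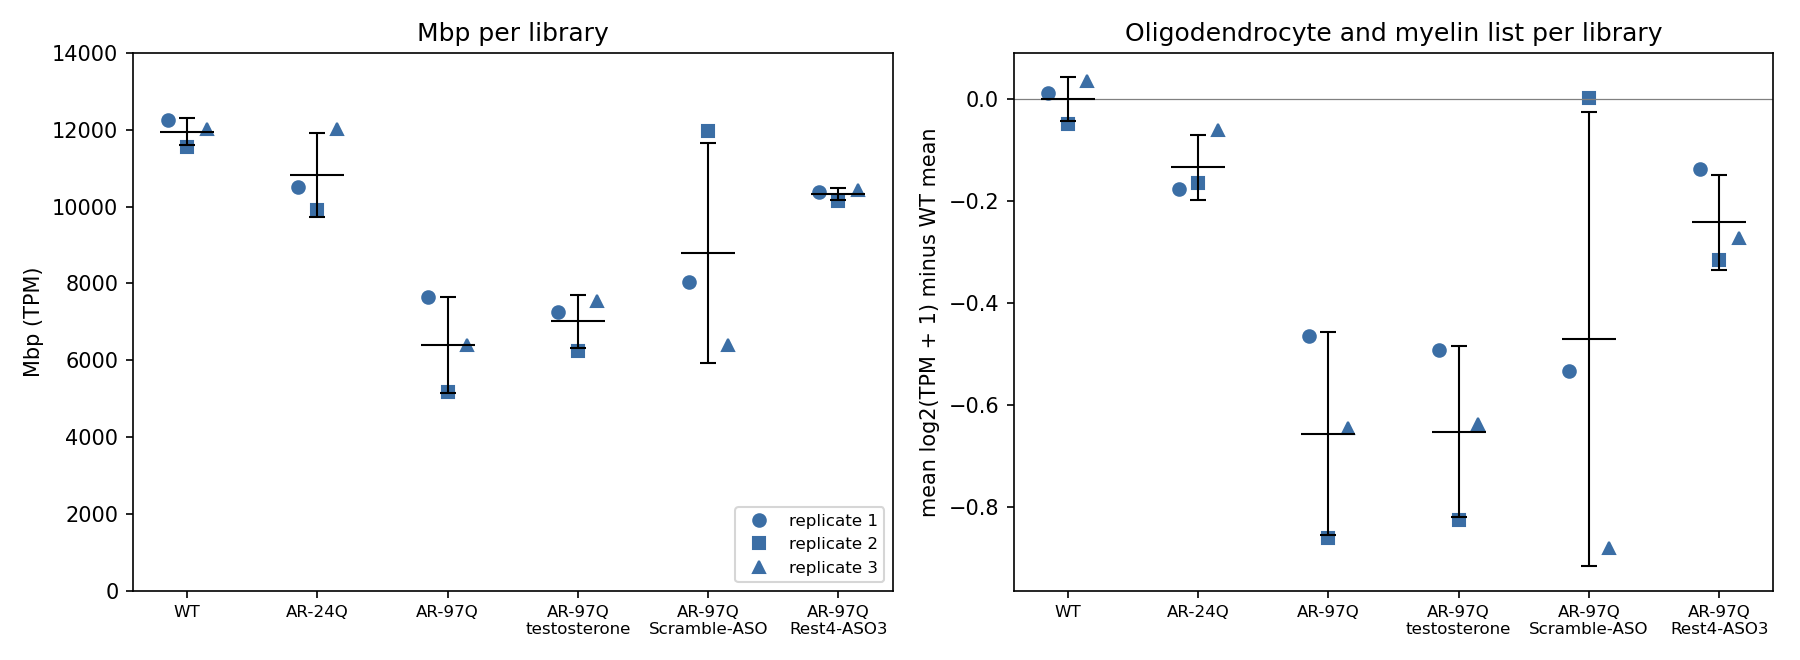
Mbp in TPM (left) and the mean log2(TPM + 1) of 18 oligodendrocyte and myelin markers minus the WT mean (right) for each library of 6 groups, with the group mean and SD as bars. WT libraries hold 11559 to 12255 TPM of Mbp and AR-97Q libraries 5159 to 7657, and Scramble-ASO libraries spread from 6383 to 11961. AR-24Q and the oligonucleotide groups come from tables made separately.

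The second comparison asked what testosterone, the ligand of the androgen receptor, changed in AR-97Q mice. The labels record no treatment for the AR-97Q group, so the act of treatment cannot be told apart from testosterone itself. Myelin genes had much the same levels in both groups. Mbp had 7007 ± 691 TPM with testosterone and 6405 ± 1249 without (SD, n = 3; limma, adjusted p = 0.61). Over all genes the median difference was −0.09, and camera tests a list against the other genes, so a list near 0 can pass as higher. The myelin list had a mean of 0.00, with 10 of 18 members positive (camera, adjusted p = 0.034; adjusted p = 0.89 with an estimated correlation). Without AR-97Q replicate 2 its mean was −0.10 and without testosterone replicate 1 −0.08, and it did not pass without these or AR-97Q replicate 3, with 0.0099. Without testosterone replicate 3 it passed with a mean of −0.0030. Its mean was 0.10 without AR-97Q replicate 1 and 0.09 without testosterone replicate 2. The list also did not pass with no filter on low values, with quantile normalization (mean 0.04), with median-of-ratios scaling (0.10) or with the GC content and length trend removed (0.09). Over 16 other settings it passed in 9, and its mean ran from −0.10 to 0.10. Rest had 4.52 ± 0.48 TPM against 5.26 ± 0.42, Srrm4 8.37 ± 0.11 against 11.2 ± 2.2, and Ar 1.09 ± 0.05 against 1.31 ± 0.11 (SD, n = 3), and none of them was called. The REST target list had a median of −0.12 and did not pass (camera, adjusted p = 0.16).

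Rostral Hox genes, which mark position along the body axis, were lower with testosterone as a list. All 9 were negative with a mean of −0.46, none was called and 8 passed when adjusted over the list alone (camera, adjusted p = 1.8e-06; adjusted p = 0.71 with an estimated correlation). Hoxa5 had 39.2 ± 2.4 TPM against 66.6 ± 7.4, and Hoxc5 had 15.8 ± 2.2 against 26.3 ± 4.6 (SD, n = 3). A difference between the groups in the level of cord sampled was not tested. The 5 erythroid markers tested were positive with a mean of 0.61 and none was called (camera, adjusted p = 1.8e-06; adjusted p = 0.71 with an estimated correlation). The haemoglobin genes Hbb-bs, at 1960 ± 221 against 1315 ± 772 TPM, and Hbb-bt, at 1001 ± 156 against 632.1 ± 399.2 (SD, n = 3), are near-identical copies whose separate values are uncertain. The erythroid mean was 0.39 without AR-97Q replicate 1, 0.38 without AR-97Q replicate 2 and 1.06 without AR-97Q replicate 3. All 23 cytosolic ribosomal protein genes were positive with a mean of 0.07 (camera, adjusted p = 4.9e-10; adjusted p = 0.86 with an estimated correlation), and 10 of 14 cholesterol synthesis genes were positive with a mean of 0.06 (camera, adjusted p = 4.5e-05; adjusted p = 0.88 with an estimated correlation). With the median of all genes at −0.09, passing upward with a small mean need not mean a rise, and negative signs were the more common. The ribosomal protein mean was 0.12 without testosterone replicate 1 and 0.03 without testosterone replicate 3, and the cholesterol mean 0.13, 0.04 and 0.02 without AR-97Q replicates 1, 2 and 3. Rescaling without mitochondrial and ribosomal RNA gave 0.12 and 0.11, and median-of-ratios scaling 0.17 and 0.16. The cholesterol mean was 0.12 with quantile normalization and 0.16 with the GC content and length trend removed. All 21 voltage-gated channel genes were negative with a mean of −0.23 (camera, adjusted p = 0.0074; adjusted p = 0.89 with an estimated correlation), a list that did not pass without testosterone replicate 2 or testosterone replicate 3, with means of −0.17 and −0.21. With the GC content and length trend removed its mean was −0.07 and it did not pass (camera, adjusted p = 0.17). The mean was −0.14 with quantile normalization and −0.13 with median-of-ratios scaling, and the list passed in 13 of 16 other settings, with adjusted p from 3.7e-05 to 0.17 by camera. The 18 oxidative phosphorylation genes had a mean of 0.02, 9 of them positive (camera, adjusted p = 0.0025; adjusted p = 0.89 with an estimated correlation), and did not pass without AR-97Q replicate 2 or testosterone replicate 3, where the mean was −0.00 and −0.01. It was 0.05 without AR-97Q replicate 1 and 0.04 without testosterone replicate 1 or testosterone replicate 2. Quantile normalization, with a mean of 0.04, also ended this call, and the mean was 0.07 rescaled, 0.12 with median-of-ratios scaling and 0.06 with the GC content and length trend removed.

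Of the 7 lists that passed camera, 0 passed fry (adjusted p = 0.11 to 0.99). Of 16117 genes, 2 were called between testosterone and AR-97Q. Snord49b, a small nucleolar RNA, was higher at 6.42 ± 0.17 against 3.07 ± 0.20 TPM, and Mir7026 was lower at 2.87 ± 1.01 against 13.4 ± 3.4 (SD, n = 3; limma, adjusted p = 0.030 for both). Testosterone replicate 1 held 37.7 TPM of Xist, a transcript of female cells. Snord49b and Mir7026 are small RNA genes, which an mRNA kit is not made to capture. Mir10b, Nfat5 and Npas4 had the next smallest p and did not pass (limma, adjusted p = 0.079, 0.13 and 0.13). At an unadjusted p under 0.05 there were 2171 genes, 2009 (92.5%) of them lower. That share depended on scaling and was 79.4% rescaled without mitochondrial and ribosomal RNA, 61.9% with the GC content and length trend removed, 54.8% with median-of-ratios scaling and 53.8% with quantile normalization. The count of called genes was 751 without AR-97Q replicate 1 (19 higher, 732 lower), 1 without testosterone replicate 1 (Mir7026), 1 without testosterone replicate 2 (LOC115488130, not among the 2), and 0 without AR-97Q replicate 2, AR-97Q replicate 3 or testosterone replicate 3. It was also 0 with the 2 groups alone, with a minimum mean of 10 TPM or without small RNA genes, and 1 with quantile normalization (Snord49b) or with no filter on low values (Gm39193, not among the 2).

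Treated transgenic mice were also compared with WT. The myelin genes were lower, with Mbp at 7007 ± 691 against 11948 ± 355 TPM, Mag at 494.9 ± 55.7 against 866.2 ± 29.5 and Cldn11 at 373.3 ± 43.5 against 595.3 ± 5.5 (SD, n = 3). Of 18 myelin markers, 15 were called lower and 18 when adjusted over the list alone, with a mean of −0.65 (camera, adjusted p = 9.6e-20; adjusted p = 0.35 with an estimated correlation). The precursor list had a mean of −0.30 with Sox10 called lower, and 4 of 5 passed when adjusted over the list alone (camera, adjusted p = 0.0011; adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis genes had a mean of −0.19, with 3 of 14 called lower and 8 when adjusted over the list alone (camera, adjusted p = 5.7e-05). Astrocyte markers had a mean of −0.23, with 2 of 11 called lower and 5 when adjusted over the list alone, and rostral Hox genes a mean of −0.37, with 3 of 9 and 5 (camera, adjusted p = 0.00032 for both). Vascular markers had a mean of −0.28, with 1 of 9 called lower and 3 when adjusted over the list alone (camera, adjusted p = 0.00023). Immediate early genes had a mean of −0.40, with 3 of 10 called lower and 4 when adjusted over the list alone (camera, adjusted p = 0.0022). Each of these 5 lists had adjusted p = 0.35 with an estimated correlation. Over genes of at least 10 TPM the immediate early list had a mean of −0.20 and did not pass. These 7 lists passed fry (adjusted p = 0.027 to 0.046), and the other 5 lists that passed camera did not (adjusted p = 0.13 to 0.18). The called immediate early genes, which respond to cell activity, were Npas4 at 1.55 ± 0.09 against 4.50 ± 1.02 TPM, Nr4a1 at 8.73 ± 0.14 against 12.5 ± 0.7 and Fos at 5.44 ± 0.76 against 9.95 ± 3.01 (SD, n = 3).

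In the higher direction, 5 of 5 erythroid markers (mean 0.82) and 12 of 12 cell cycle genes (mean 0.17) were positive with none called, 4 and 0 of them passing when adjusted over the list alone (camera, adjusted p = 0.00032 and 0.00066; adjusted p = 0.35 and 0.37 with an estimated correlation). All 23 ribosomal protein genes were positive with a mean of 0.11, and 0.06 without testosterone replicate 3 (camera, adjusted p = 1.2e-05; adjusted p = 0.45 with an estimated correlation). Ependymal markers, with a mean of 0.38, and brain markers, with a mean of 0.27, also passed (camera, adjusted p = 0.0020 and 0.038), both with adjusted p = 0.35 with an estimated correlation. The cell cycle and ependymal lists did not pass without WT replicate 3, with means of 0.11 and 0.29. The brain list did not pass without WT replicate 1, testosterone replicate 1 or testosterone replicate 3, with means of 0.18, 0.27 and 0.20, and its mean was 0.17 with no filter on low values. Cd24a, a cell surface glycoprotein, rose to 148.6 ± 12.4 from 92.6 ± 1.9 TPM, and Cyp26b1 to 9.20 ± 0.72 from 4.21 ± 0.56 (SD, n = 3). Nefh, the heavy neurofilament gene of large axons, fell to 190.4 ± 16.9 from 259.9 ± 35.9 TPM (SD, n = 3) and was the called member of 14 motor neuron markers, a list that did not pass (camera, adjusted p = 0.13). Syt4, higher at 96.7 ± 9.7 against 70.1 ± 8.2 TPM (SD, n = 3), was the called member of the REST target list, which did not pass (camera, adjusted p = 0.10). Kcna1 and Col1a2 were called lower and Cdkn1a higher, and their lists of voltage-gated channels, meningeal markers and steroid receptor responsive genes did not pass (camera, adjusted p = 0.063, 0.057 and 0.23). In all, limma called 411 genes, 72 higher and 339 lower, with 2941 at an unadjusted p under 0.05, 67.1% of them lower. Quantile normalization gave 178 higher and 307 lower calls, with 48.6% lower at that p, and median-of-ratios scaling 162 and 318, with 52.5%. Rescaling gave 136 and 352, with 58.9%, and removing the GC content and length trend 229 and 371, with 52.2%. The count was 227 without WT replicate 1, 57 without WT replicate 2, 146 without WT replicate 3, 50 without testosterone replicate 2, 49 without testosterone replicate 3 and 15 with no filter on low values.

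**Figure D2:**
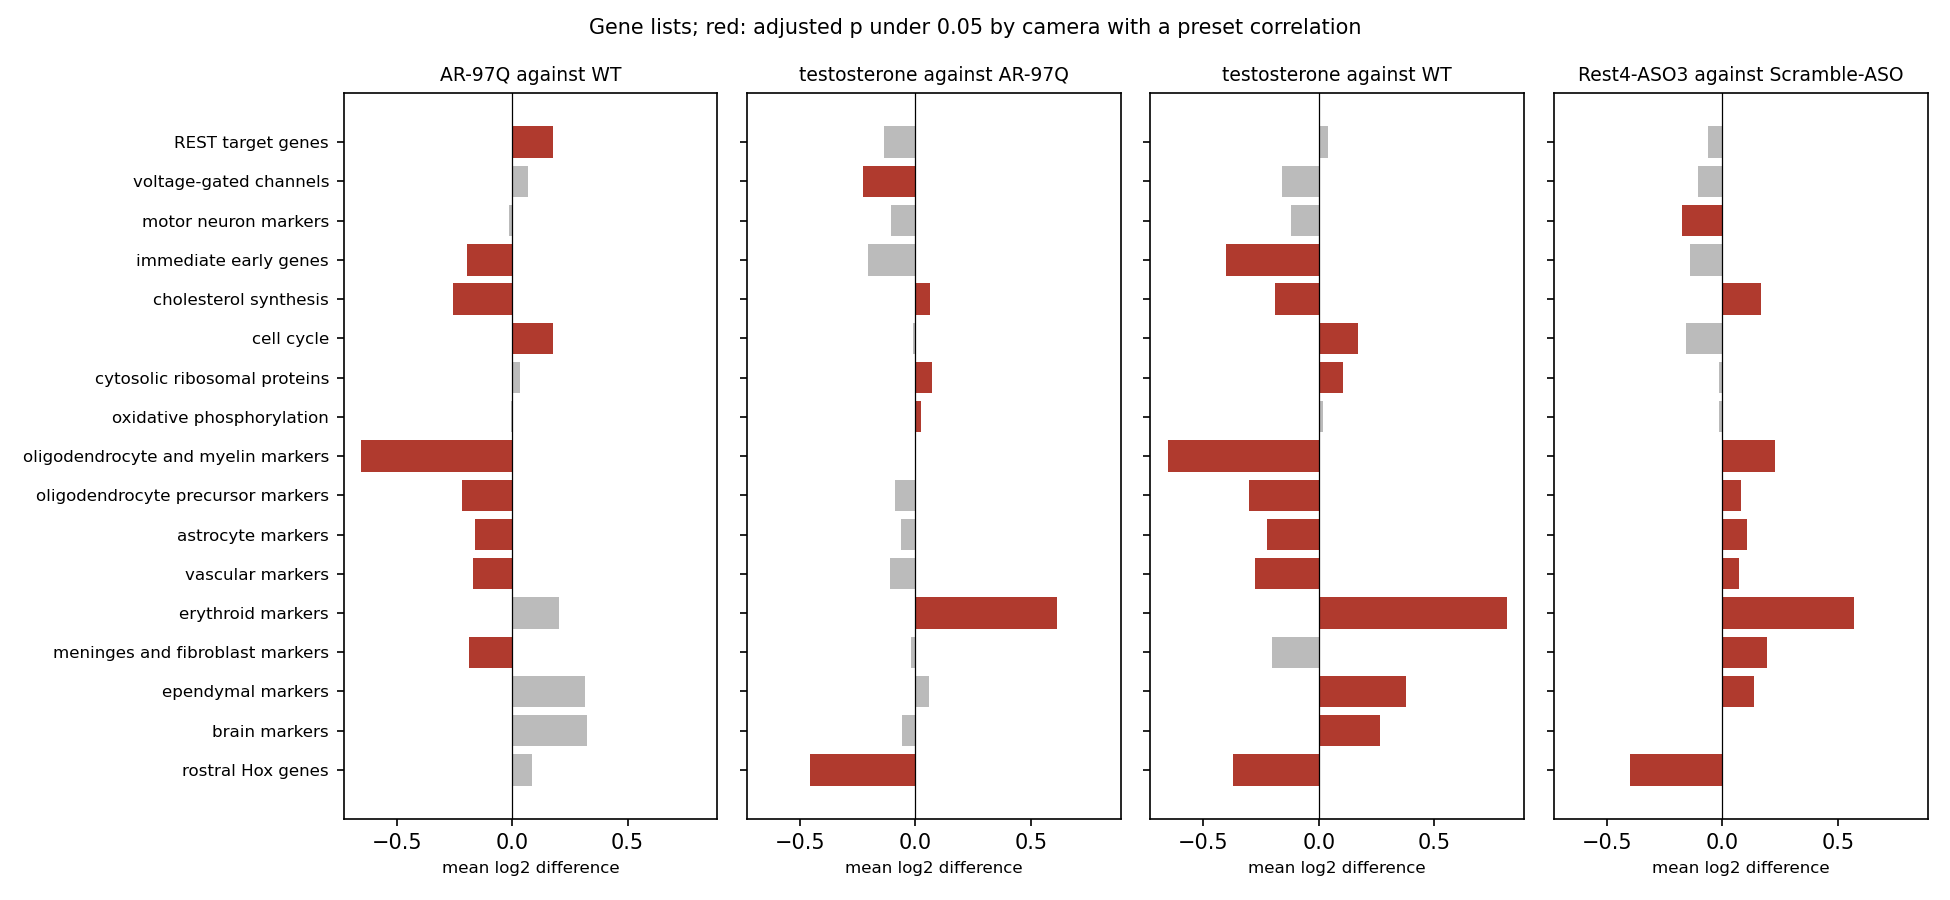
Mean log2 difference of each gene list that passed in at least 1 comparison, with the comparison above each panel and red bars for an adjusted p under the threshold by camera with a preset correlation. A list with fewer than 3 tested members has no bar. With an estimated correlation 0 lists passed in any of the panels.

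The oligonucleotide comparison asked what Rest4-ASO3 changed in AR-97Q mice against Scramble-ASO. The target was not lower at the level of the gene. Rest had 3.78, 3.55 and 4.48 TPM in the Rest4-ASO3 libraries and 3.73, 3.39 and 3.42 in the Scramble-ASO libraries (limma, adjusted p = 0.82), and a gene value does not separate the Rest4 form from other forms. Srrm4 had 7.09 ± 0.86 against 8.47 ± 1.42 TPM and Ar 1.28 ± 0.20 against 1.29 ± 0.19 (SD, n = 3). Myelin genes were positive as a list, with all 18 members positive, none called and a mean of 0.23 (camera, adjusted p = 1.7e-10; adjusted p = 0.56 with an estimated correlation). Mbp had 10327 ± 151 TPM with Rest4-ASO3 and 8789 ± 2867 with Scramble-ASO (SD, n = 3; limma, adjusted p = 0.76). Scramble-ASO replicate 2 held 11961 TPM of Mbp and replicate 3 held 6383. The list rested on Scramble-ASO replicate 3, since without it the mean was 0.02 and the test was not passed, while without Scramble-ASO replicate 2 the mean was 0.47.

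Of 14 cholesterol synthesis genes 13 were positive, with a mean of 0.17, and 0.10 without Scramble-ASO replicate 3 (camera, adjusted p = 5.5e-14; adjusted p = 0.24 with an estimated correlation), and 10 of 11 astrocyte markers were positive, with a mean of 0.11, and 0.16 with median-of-ratios scaling (camera, adjusted p = 2.4e-06; adjusted p = 0.15 with an estimated correlation). Aqp4, the water channel of astrocytes, had 379.4 ± 32.8 against 299.7 ± 20.6 TPM (SD, n = 3) and did not pass over all genes. The 5 erythroid markers had a mean of 0.57, and all 5 passed when adjusted over the list alone (camera, adjusted p = 1.1e-10; adjusted p = 0.24 with an estimated correlation). Meningeal and fibroblast markers had a mean of 0.20, with 4 of 9 passing when adjusted over the list alone (camera, adjusted p = 3.3e-05; adjusted p = 0.15 with an estimated correlation), a list that did not pass over genes of at least 10 TPM, with a mean of 0.0089. Rostral Hox genes were negative in 9 of 9 with a mean of −0.40 (camera, adjusted p = 0.00050; adjusted p = 0.62 with an estimated correlation), and Hoxa5 had 50.2 ± 22.9 against 85.7 ± 9.7 TPM (SD, n = 3). The Hox mean was −0.26 without Rest4-ASO3 replicate 1 and −0.60 without Rest4-ASO3 replicate 2. Here too, a difference in the level of cord sampled was not tested. Motor neuron markers were negative in 13 of 14 with a mean of −0.17 (camera, adjusted p = 0.014; adjusted p = 0.64 with an estimated correlation), and that list did not pass without Scramble-ASO replicate 1, Scramble-ASO replicate 2 or Rest4-ASO3 replicate 1, with means of −0.12, −0.16 and −0.11.

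The precursor, vascular and ependymal lists, with means of 0.08, 0.07 and 0.14, passed (camera, adjusted p = 0.014, 0.0066 and 0.030), with adjusted p = 0.50, 0.62 and 0.51 with an estimated correlation. The median of all genes was −0.05 in this comparison. The precursor list did not pass without Scramble-ASO replicate 3, with a mean of 0.02, or with no filter on low values. Its mean was 0.13 without Scramble-ASO replicate 1, 0.14 with median-of-ratios scaling and 0.16 with the GC content and length trend removed. The vascular list did not pass without Scramble-ASO replicate 2, where the mean turned to −0.0050, or without Rest4-ASO3 replicate 2, where it was 0.01. Its mean was 0.13 without Scramble-ASO replicate 3, 0.15 without Rest4-ASO3 replicate 1 and 0.04 over genes of at least 10 TPM. It was 0.14 with quantile normalization and 0.13 with median-of-ratios scaling or the GC content and length trend removed. The ependymal list passed in 6 of 14 other settings, with adjusted p from 0.0036 to 0.56 by camera. It did not pass without Scramble-ASO replicate 1, Scramble-ASO replicate 2 or Rest4-ASO3 replicate 1, with means of 0.10, 0.11 and 0.05, and its mean was 0.21 without Rest4-ASO3 replicate 2. It also did not pass with no filter on low values, quantile normalization, rescaling, median-of-ratios scaling or the GC content and length trend removed (camera, adjusted p = 0.12, 0.072, 0.065, 0.10 and 0.12). Of the 10 lists that passed camera, 0 passed fry (adjusted p = 0.21 to 0.72). The REST target list had a median of −0.08 and did not pass (camera, adjusted p = 0.34). With limma, 0 of 15960 genes were called, and 1040 had an unadjusted p under 0.05, 872 (83.8%) of them lower. That share was 72.3% rescaled, 51.6% with median-of-ratios scaling, 51.0% with the GC content and length trend removed and 49.1% with quantile normalization. The count of called genes was 2 without Rest4-ASO3 replicate 1, Gdf1 and Cers1, overlapping genes whose separate values are uncertain. Mir7019 had the smallest adjusted p, 0.088 by limma.

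The oligonucleotide was also compared with the transgene effect, gene by gene and with no library in common. Of the 112 genes called in AR-97Q against WT, 100 (89.3%) had the opposite sign in Rest4-ASO3 against Scramble-ASO. These were 65 of the 71 lower genes and 35 of the 41 higher genes, while the median of all genes in the oligonucleotide comparison was −0.05. The share rested on Scramble-ASO replicate 3: without it 49.1% had the opposite sign. Over the called genes the correlation across genes was −0.53, and −0.12 without Scramble-ASO replicate 3. Over the 15804 genes tested in both it was −0.18, and −0.03 without that library, −0.29 without Scramble-ASO replicate 2 and −0.33 over genes of at least 10 TPM. These correlations are across genes, which are not independent replicates. Of the 10 splits of the 6 oligonucleotide libraries, the real one included, 4 gave as large a share of either sign, with a highest other of 95.5%. As large a correlation in size came from 4 splits over all genes and 2 over called genes, with a highest other of 0.30 and 0.54.

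**Figure D3:**
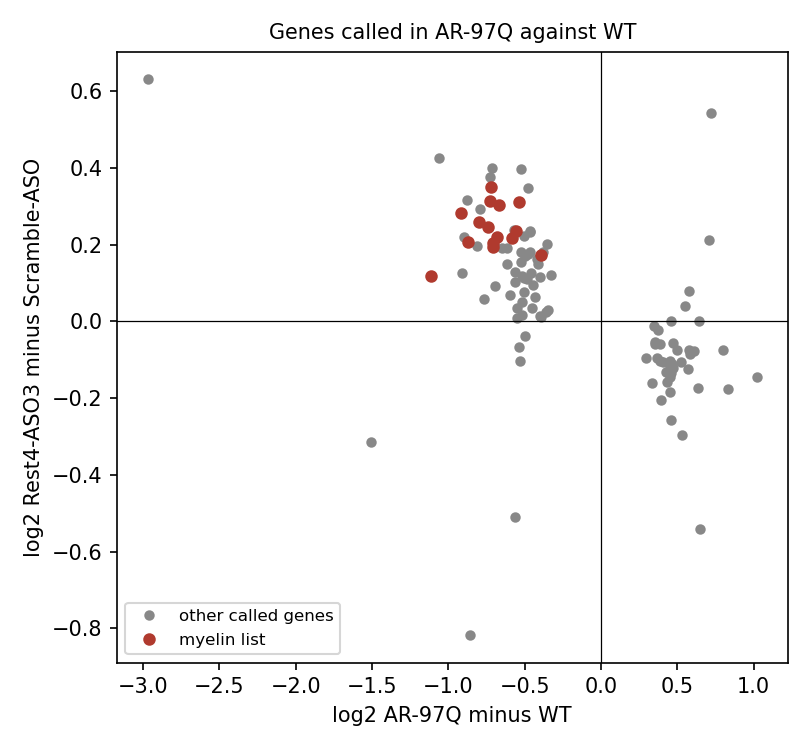
Log2 difference of Rest4-ASO3 minus Scramble-ASO against that of AR-97Q minus WT for the 112 genes called in the latter, 1 point per gene, with myelin list members in red. The genes with opposite signs number 100, and the share is 49.1% without Scramble-ASO replicate 3.

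Testosterone and the transgene effect share the AR-97Q libraries, which alone gives a negative correlation. Across 16117 genes the correlation was −0.30, against −0.50 in simulations with no effect, and the covariance was −0.011 against −0.013. Without AR-97Q replicate 1 the correlation was −0.49, against −0.60 in simulations of those libraries, and the covariance −0.025 against −0.017. Genes varied independently in these simulations, with no transgene effect and no shift shared within a library. They are therefore no firm reference for the real libraries, and no relation is read from the difference. Of the called genes, 37 of 41 higher genes had a negative testosterone difference, while the median of all genes was −0.09, and 33 of 71 lower genes had a positive one. AR-97Q and testosterone-treated AR-97Q share the WT libraries. They had 62 lower and 20 higher called genes in common. Independent lists would share 1.5 and 0.18, which leaves out the shared WT libraries, and 20 simulations with no effect shared a mean of 0, which leaves out the effects, so neither is a reference for the observed overlap. Their covariance was 0.027 against 0.013 simulated, and part of the overlap may come from the shared WT libraries.

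AR-24Q, the transgene with a shorter glutamine stretch, held 10820 ± 1089 TPM of Mbp and 3634 ± 108 of Plp1, the most abundant membrane protein gene of myelin, beside 11948 ± 355 and 4118 ± 26 in WT and 6405 ± 1249 and 2493 ± 442 in AR-97Q (SD, n = 3). The myelin list lay 0.13 below WT in AR-24Q on the log2 scale, with libraries at −0.18, −0.16 and −0.06, and −0.065 from it with median-of-ratios scaling. Other lists lay further from WT in AR-24Q, in both directions, on the scale of the TPM as deposited. In AR-24Q replicate 3, 18S ribosomal RNA made up 8.74% of TPM, which lowers the other values of that library. Lower lists were motor neuron markers at −0.42 ± 0.11, rostral Hox genes at −0.31 ± 0.59, vascular markers at −0.29 ± 0.36, immediate early genes at −0.26 ± 0.13, meningeal markers at −0.24 ± 0.28, precursor markers at −0.20 ± 0.15, cell cycle genes at −0.18 ± 0.20, cholesterol synthesis genes at −0.17 ± 0.08 and astrocyte markers at −0.15 ± 0.12 (SD, n = 3). Erythroid markers at 0.30 ± 0.40 and ependymal markers at 0.17 ± 0.41 (SD, n = 3) had positive means. AR-97Q lay below AR-24Q by −0.52. Rest had 4.66 ± 0.70 TPM, Srrm4 7.84 ± 0.69 and Ar 1.31 ± 0.28 in AR-24Q (SD, n = 3). The REST target list lay at −0.02 ± 0.10 (SD, n = 3) from the WT mean. AR-24Q values come from a table made separately, so table and group cannot be told apart, and no test was made.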

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

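Xist, the transcript that silences one X chromosome in females, stood at 37.7 TPM in testosterone replicate 1, against 0 to 0.069 in the other 17 libraries. The 5 sex-linked genes were tested in both testosterone comparisons, with medians of −1.36 against AR-97Q and −1.35 against WT, and the list did not pass (camera, adjusted p = 0.71 and 0.33). It stood out as the level of a single library, in a gene that no comparison was about. The summed Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 0 in that library and at 81.7 to 137.2 TPM in the other 17. The testosterone group holds 1 library with this female pattern and 2 without it. Without that library, 1 gene was called between testosterone and AR-97Q and 407 between testosterone and WT, against 2 and 411 with it.

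The 18S ribosomal RNA row made up 8.74% of TPM in AR-24Q replicate 3, against 0.12% to 0.92% in the other 17 libraries. AR-24Q libraries entered no test. Mbp in that library was 12027 TPM, beside 10520 and 9912 in the other AR-24Q libraries.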

How the results depend on the processing

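Rescaling without mitochondrial and ribosomal RNA, leaving out small RNA genes, removing the GC content and length trend and, except for AR-24Q and for the relation of the effects, median-of-ratios scaling and a minimum mean of 10 TPM were chosen after the data were seen, as were the list tests outside the estimated correlation, the block and the left-out libraries. The others were chosen before. Median-of-ratios factors with edgeR, DESeq2 and the filters on counts were not run, because the tables hold TPM. TPM gives no depth, so what depth limits could not be measured. Where no reason is named, the cause was not tested.

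For AR-97Q against WT, the 112 calls became 5 with a fold threshold, 0 with no filter on low values, which tests more genes, 1 with the 2 groups alone, which has fewer libraries, 184 with quantile normalization (60 higher, 124 lower; 103 shared) and 263 with the GC content and length trend removed (81 and 182). Median-of-ratios scaling gave 147 (38 and 109). Leaving out each library gave 0 to 216. For testosterone against AR-97Q there were 2 calls, 1 of them kept with a fold threshold and 1 with quantile normalization. No filter gave 1 call and leaving out testosterone replicate 2 gave 1, neither among the 2. The count was 0 with the 2 groups alone, 0 with a minimum mean of 10 TPM, 0 without small RNA genes, and 0 to 751 with a library left out. For testosterone against WT, the 411 calls became 28 with a fold threshold, 15 with no filter and 49 to 407 with a library left out. Scaling moved the higher and lower calls from 72 and 339 to 178 and 307 (quantile), 162 and 318 (median-of-ratios), 136 and 352 (rescaled without mitochondrial and ribosomal RNA) and 229 and 371 (GC content and length). For Rest4-ASO3 against Scramble-ASO, leaving out a library gave 0 to 2 calls.

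The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated from −0.076 to 0.103 over 12 pairs. With the replicate number as a block, the calls were 127, 0, 422 and 1 in the 4 comparisons, against 112, 2, 411 and 0. The cell cycle list in AR-97Q against WT, with a mean of 0.18, did not pass with the block (camera, adjusted p = 0.055, and 0.00025 to 0.48 over its 16 other settings). Of the lists that passed without it, 8 of 9, 7 of 7, 12 of 12 and 10 of 10 passed with it. Of the named genes, Lss in AR-97Q against WT, Snord49b and Mir7026 in testosterone against AR-97Q, and Kcna1, Nefh, Fos, Dhcr24 and Hoxa5 in testosterone against WT were called without the block and not with it. Syt4 and Aqp4 in AR-97Q against WT, Olig1 and Neurod6 in testosterone against WT and Mir7019 in Rest4-ASO3 against Scramble-ASO were called with it and not without.

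With an estimated correlation 0 lists passed in each comparison, against 9, 7, 12 and 10. For AR-97Q against WT, 14 passed with quantile normalization and 14 with median-of-ratios scaling. With a library left out, lists passing ranged from 9 to 13 for AR-97Q against WT, 5 to 10 for testosterone against AR-97Q, 11 to 15 for testosterone against WT and 8 to 14 for Rest4-ASO3 against Scramble-ASO. The myelin list passed in 16 of 16 other settings for AR-97Q against WT, with a mean of −0.75 to −0.55, and in 16 of 16 for testosterone against WT, with −0.73 to −0.56. It passed in 9 of 16 for testosterone against AR-97Q and 14 of 15 for Rest4-ASO3 against Scramble-ASO. A minimum mean of 10 TPM, which leaves fewer members, ended the call of immediate early genes in both comparisons with WT, of cell cycle genes in AR-97Q against WT and of meningeal markers in Rest4-ASO3 against Scramble-ASO.

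The correlation of the transgene and oligonucleotide effects, −0.18, was −0.33 over genes of at least 10 TPM and −0.29 to −0.028 with a library left out. Over called genes it was −0.62 to −0.12, and the share of opposite sign 49.1% to 92.9%, the lowest without Scramble-ASO replicate 3. The correlation with testosterone was −0.49 to −0.22. The AR-24Q myelin list, −0.13 from WT, was −0.065 with median-of-ratios scaling and −0.17 to −0.11 with a library left out. AR-97Q minus AR-24Q, −0.52, was −0.65 with that scaling, −0.60 rescaled without mitochondrial and ribosomal RNA and −0.54 to −0.49 with a library left out.

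The genes named below changed sign, and none of them passed where its sign had changed. Rest in AR-97Q against WT was −0.049 (quantile), −0.016 (rescaled), −0.043 (median-of-ratios), −0.049 (GC content and length) and −0.028 to 0.070 with a library left out. In testosterone against AR-97Q, Mbp was −0.046 (quantile) and −0.0034 to 0.28 with a library left out, and Ar 0.036 and Myrf 0.0014 with the GC content and length trend removed. Ar in testosterone against WT was −0.022 to 0.21 with a library left out. In Rest4-ASO3 against Scramble-ASO, Ar was 0.037 (quantile), 0.0092 (rescaled), 0.025 (median-of-ratios), 0.077 (GC content and length) and −0.059 to 0.067 with a library left out, Pdgfra −0.070 to 0.20, Olig1 −0.032 to 0.22 and Olig2 −0.056 to 0.11. The myelin list in testosterone against AR-97Q, with a mean of 0.0040, was −0.098 to 0.10 with a library left out, and it passed at −0.0030 without testosterone replicate 3 (camera, adjusted p = 0.045).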

Other observations

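The tests on myelin genes, on Scramble-ASO replicate 2, on sex, on protein-coding genes alone and on other splits were chosen after their results or closely related values had been seen, and the scale, GC content and non-coding tests of the testosterone pattern before.

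Genes of position along the body axis differed between libraries of one group. In AR-24Q, Hoxc5 had 1.58, 18.8 and 26.9 TPM and Hoxc6 22.3, 46.4 and 61.2 in replicates 1 to 3, and Hoxc10 had 3.31, 0.92 and 0. In Rest4-ASO3, the rostral Hox list lay at −0.48, 0.20 and −0.31 from the WT mean, and in testosterone at −0.38, −0.34 and −0.40, while the 3 AR-97Q libraries lay at 0.08, 0.10 and 0.08. Hoxc10, from the list of caudal Hox genes and near the low-value filter, had 0.48, 3.29 and 1.21 TPM with testosterone and 0.14, 1.11 and 0.15 in AR-97Q. It had 3.41, 0.05 and 0.85 TPM with Rest4-ASO3 and 0.09, 0 and 0.28 with Scramble-ASO. Malat1, a nuclear non-coding RNA chosen after its values were seen, had 64.3 ± 19.1 TPM with testosterone, 120.8 ± 17.99 in AR-97Q and 136.9 ± 16.4 in WT (SD, n = 3). Low values were not particular to testosterone. Malat1 had 100.3, 86.5 and 76.6 TPM in Rest4-ASO3, 124.5, 158.0 and 110.3 in Scramble-ASO, and 89.8, 60.6 and 143.5 in AR-24Q. The lists of microglia, interferon and inflammation, heat shock and unfolded protein response, glutamatergic synapse, inhibitory synapse and presynaptic release genes passed in 0 of the 4 comparisons by camera or fry. Camera tests a list against the other genes, so its direction can differ from the mean: the inhibitory synapse list had a mean of −0.07 in testosterone against AR-97Q and an upward test (adjusted p = 0.71).

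Myelin genes were lower in AR-97Q than in WT. A change of scale in TPM would bring the list to within its spread of 0 under median-of-ratios scaling, yet its mean was −0.72 with an SD between libraries of 0.19. Removing the trend on GC content and length left −0.72, so neither accounts for the whole pattern. An equal loss of all cells of the oligodendrocyte lineage would lower the precursor list as much, yet that list lay 0.44 above the myelin list, with an SD of 0.18. The precursor list was itself lower, with a mean of −0.21, so a smaller loss across the lineage stays open. Its genes are not all particular to precursors, so the contrast does not separate precursors from mature cells. Fewer mature cells and less myelin transcript per cell also stay open as hypotheses and were not tested.

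Most genes at an unadjusted p under 0.05 were lower with testosterone than in AR-97Q (92.5%). With median-of-ratios scaling 54.8% were lower, and with the GC and length trend removed 61.9%. Both corrections set the median of all genes to about 0, which fixes the outcome. They therefore cannot tell a change of scale or GC content from a shift of the genes themselves. Mitochondrial transcripts made up 18.8%, 19.9% and 16.6% of the testosterone libraries and 16.7%, 14.7% and 15.1% of the AR-97Q libraries. Rescaling without mitochondrial and ribosomal RNA, which does not centre the median, left 79.4% lower. It moved the median of all genes from −0.087 to −0.045, so part of the shift went with the share of these RNAs. Without testosterone replicate 1, the library of the female pattern, 88.4% were lower, with a range of 6.5 percentage points over the left-out libraries. Its sex therefore does not account for the whole pattern. A lower yield of long non-coding RNA would not lower protein-coding genes, yet 1820 of the 2171 genes at that p were protein-coding and 1710 of them (93.96%) were lower. That share was 89.8% to 95.9% with a library left out. The share over all genes already fixed it at 91.1% or more, because most of the genes are protein-coding. The coding share is therefore no separate test. What argues against a lower non-coding yield, for the protein-coding genes only, is that 1710 of the lower genes were protein-coding. For the non-coding genes it stays open: their median lay −0.022 from the coding one, within its SD of 0.025. The position along the axis and treatment differences named above also stay open.

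Scramble-ASO replicate 2 lay near WT in the 71 genes lower in AR-97Q, with a mean of −0.06 against −0.45 and −0.73 in the other Scramble-ASO libraries. A swap with a Rest4-ASO3 library was predicted to put one of these at or below −0.45. The lowest Rest4-ASO3 score was −0.32, with an SD of 0.06 between the Rest4-ASO3 libraries. The other Scramble-ASO libraries lay so far apart that −0.45 is no firm bound, so this cannot decide on a swap. A single wrong label stays open: mouse Ar was 1.498 TPM, above the 1.05 to 1.42 of the other 5 libraries, which was first read as pointing to a wrong label and then set aside, since 1 gene near the low-value filter decides nothing and chance puts a library outside the other 5 in 33.3% of cases. A biological difference between samples was not tested.

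The 10 splits of 6 libraries are too few for a share under 0.05, and the smallest exact p they allow is 0.1. The real and the highest other split called 112 and 1 genes in AR-97Q against WT, 2 and 1 in testosterone against AR-97Q, 411 and 1 in testosterone against WT, and 0 and 2 in Rest4-ASO3 against Scramble-ASO. As many genes as in the real split came from 1, 1, 1 and 10 of the 10 splits, the real one included.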
